A study of Mus musculus with 20 samples.

How the data were processed

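Genomic DNA from the tails of 10 C57BL/6 mice of 1 family was compared with DNA of 1 reference male of the same colony by array comparative genomic hybridisation, in which mouse and reference DNA carry different dyes and compete for the same probes. The family held a male parent, a female parent and 8 progeny. Each mouse was hybridised to 2 arrays with the dyes Cy3 and Cy5 exchanged, giving 20 arrays. The 2 arrays of a mouse share its DNA and counted as 1 replicate, so each parent had 1 value and the progeny group had 8. The series title describes exposure of males to gamma rays at 1 mGy per day for 400 days, while its design text calls the male parent non-irradiated. Because the sources differ, no result is attributed to exposure, and no unexposed family was analysed here.

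The deposited scanner files were made with Agilent Feature Extraction 10.7.1.1, per the file headers. Each holds processed green and red intensity values, which per the file headers were background-subtracted, spatially detrended and scaled by a linear dye factor. The deposited log10 ratio of red over green was recomputed from these intensities to within 1e-06 on every array. Probe positions are on mouse build mm9, per the file headers. The deposited series table holds log2 ratios. Set against the scanner values, its columns run as reference over mouse, opposite to the direction used here, and their medians lie between -0.01 and 0.01. Its scale was log2, and any further centring remained unknown.

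Log2 ratios were computed from the processed intensities, turned to mouse over reference and centred on the autosomal median of each array, without loess or quantile normalisation. Control spots and outlier spots (110 to 351 per array) were left out, and spots of 1 probe were averaged. This left 950749 distinct probes, of which 950622 were autosomal, with a median spacing of 2053 bp. The array carried only 68 distinct X and 23 Y probes. No spot was saturated. Between 75 and 3753 spots per array were not well above background in at least 1 channel. The scanner's signal over noise ran from 43.5 to 123 in green and from 39.0 to 109 in red. The number of mice, not of probes, limits the precision of statements about groups.

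Copy number calls came from an interval score modelled on ADM-2. The mean of both dye orientations was divided by a robust SD from differences of neighbouring probes. Intervals of 3 to 1000 consecutive probes were called at a score of at least 6 and a mean of at least 0.25 in size, with a mean of at least 0.25 in the same direction in each orientation. Overlapping calls were merged into regions, and each region was measured again in all mice. A region was progeny only where a progeny was called and both parents stayed under 0.25 in that direction. Transmission from a single carrying parent was tested against 1 in 2, which assumes a parent with the variant on 1 copy, with a two-sided exact binomial test and Benjamini-Hochberg adjustment, and carriers were counted by the same limit of 0.25. Probes with a shifted mean over the mice were tested with limma 3.58.1 in R 4.3.3, with 1 value per mouse, an adjusted p under 0.05 and a mean of at least 0.25 in size. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.

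False calls were estimated from the difference between dye orientations, after removing each probe's mean difference over the mice, and from the real values with probes placed in random order within each chromosome. The caller was tested on simulated data by adding segments to the randomly ordered values of every mouse. In the progeny, 3-probe losses of -0.9 were recovered in 200 of 200 cases and 3-probe gains of 0.5 in 183 of 200. The limma test was tested on 100000 simulated probes. It called 99.5% of probes shifted by -0.5 and 96.5% of those shifted by 0.35, and 1 of 99600 unshifted probes. The simulated values were drawn independently for each mouse, whereas most of the real mice were correlated. These rates therefore do not carry over directly to the real values.

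Up to 8 regions of each class with the highest absolute interval score were named by a rule fixed before the data were examined. The region of chromosome 14 from 53387255 was added after its values were seen. Gene names are not given: the scanner files pair probes with positions and not with genes, and the gene table at hand is on another build, so neither the 12 planned gene lists nor the planned single genes were analysed. A correction for GC content was not run, as no genome of the array build was used here. The normexp alternative used median spot signals in place of the planned mean spot signals. Alternatives covered the signals, slow waves, dim and saturated probes, score, probe and size thresholds, the orientation rule, single orientations, the parent limit and merging. A minimum of 10 probes and leaving out progeny 8 were added after the data were examined, as was a scan for long, low intervals of at least 30 probes with a mean of at least 0.08 in size and a score of at least 8.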

Results

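Tail DNA of 1 mouse family, comprising 2 parents and 8 progeny, was screened for copy number differences from a single reference male. Values are log2 ratios of mouse over reference, averaged over both dye orientations, and the error given for a region is the standard error over its probes. This error describes measurement within a mouse, because each mouse gave 1 value. The arrays were scanned on 5 days. Both parents shared the first day and each later day held 2 progeny, so generation and scan day cannot be told apart. The robust SD of single probes ranged from 0.081 in the male parent to 0.127 in progeny 5.

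The dose of the sex chromosomes was examined first, because the female parent against a male reference gives a known contrast on X. Her median X ratio was 0.93, with 0.92 and 0.94 in the 2 orientations, and her median Y ratio was -2.25. The size of her Y ratio depended on the processing, at -0.59 with normexp and -1.27 without dim probes. The male parent had 0.00 on X and 0.03 on Y. Progeny 1 to 4 lay between -0.01 and 0.03 on X. Progeny 5 to 8 had X ratios of 0.96, 0.96, 0.94 and 0.96, and Y ratios from -2.74 to -2.30. No whole autosome was shifted: all 190 medians, 1 per mouse and autosome, lay between -0.01 and 0.01, and 0 met the limit of 0.1 in both orientations.

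The comparison of progeny with parents asked which copy number differences appeared in progeny and in neither parent. The longest regions classed as progeny only by the limit of 0.25 were 3 of more than 30 probes. On chromosome 5, a segment from 73672030 to 73814566 (mm9, 63 probes, 143 kb) was gained in progeny 1, at 0.56 ± 0.016, and in progeny 3, at 0.56 ± 0.014. A further segment on the same chromosome, from 77615259 to 77689236 (33 probes, 74.0 kb), was gained in the same progeny, at 0.53 ± 0.029 and 0.54 ± 0.020. The remaining progeny lay between -0.02 and 0.00 in the first segment and between -0.02 and 0.05 in the second. The male parent was at 0.00 and -0.02. The female parent was at 0.14 ± 0.013 and 0.15 ± 0.020, below the limit of 0.25 in both segments but above 0 in both orientations, and a shorter interval inside the first segment passed the call limits in this parent. With the parent limit lowered to 0.15, the number of progeny-only regions fell from 1544 to 1002, and the second chromosome 5 segment was no longer progeny only.

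On chromosome 12, a segment from 56189969 to 56256271 (34 probes, 66.3 kb) was lost in progeny 1, at -0.71 ± 0.039. The parents were at -0.03 and -0.02, and the other progeny lay between -0.05 and 0.02, although a shorter interval inside the segment was called in progeny 8. The preceding probe ended at 56185028 and the next began only at 56368938, so the right end of this loss was located less closely than the left. The chromosome 5 segments in progeny 3 and the chromosome 12 segment in progeny 1 were called under each of the 13 alternative settings that changed any call, although several of these only loosened a limit or set a probe minimum below the length of the segments. The chromosome 12 loss could also come from a variant for which both parents and the reference were all heterozygous. If this variant were a loss, progeny 1 would keep no copy there. Y ratios of the female parent and progeny 5 to 8 were -2.74 to -2.25, so -0.71 argues against that. This depends on the processing, because her Y ratio was -0.59 with normexp. If the variant were a gain, the ratios do not separate it from a change that arose in the progeny. Such a gain would also be likely to part the other progeny, which lay between -0.05 and 0.02. For the chromosome 5 gains, a variant for which both parents and the reference were all heterozygous would leave the female parent at the level of the reference. Her values of 0.14 ± 0.013 and 0.15 ± 0.020 argue against it there, although a wave as short as the segments was not excluded.

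**Figure D1:**
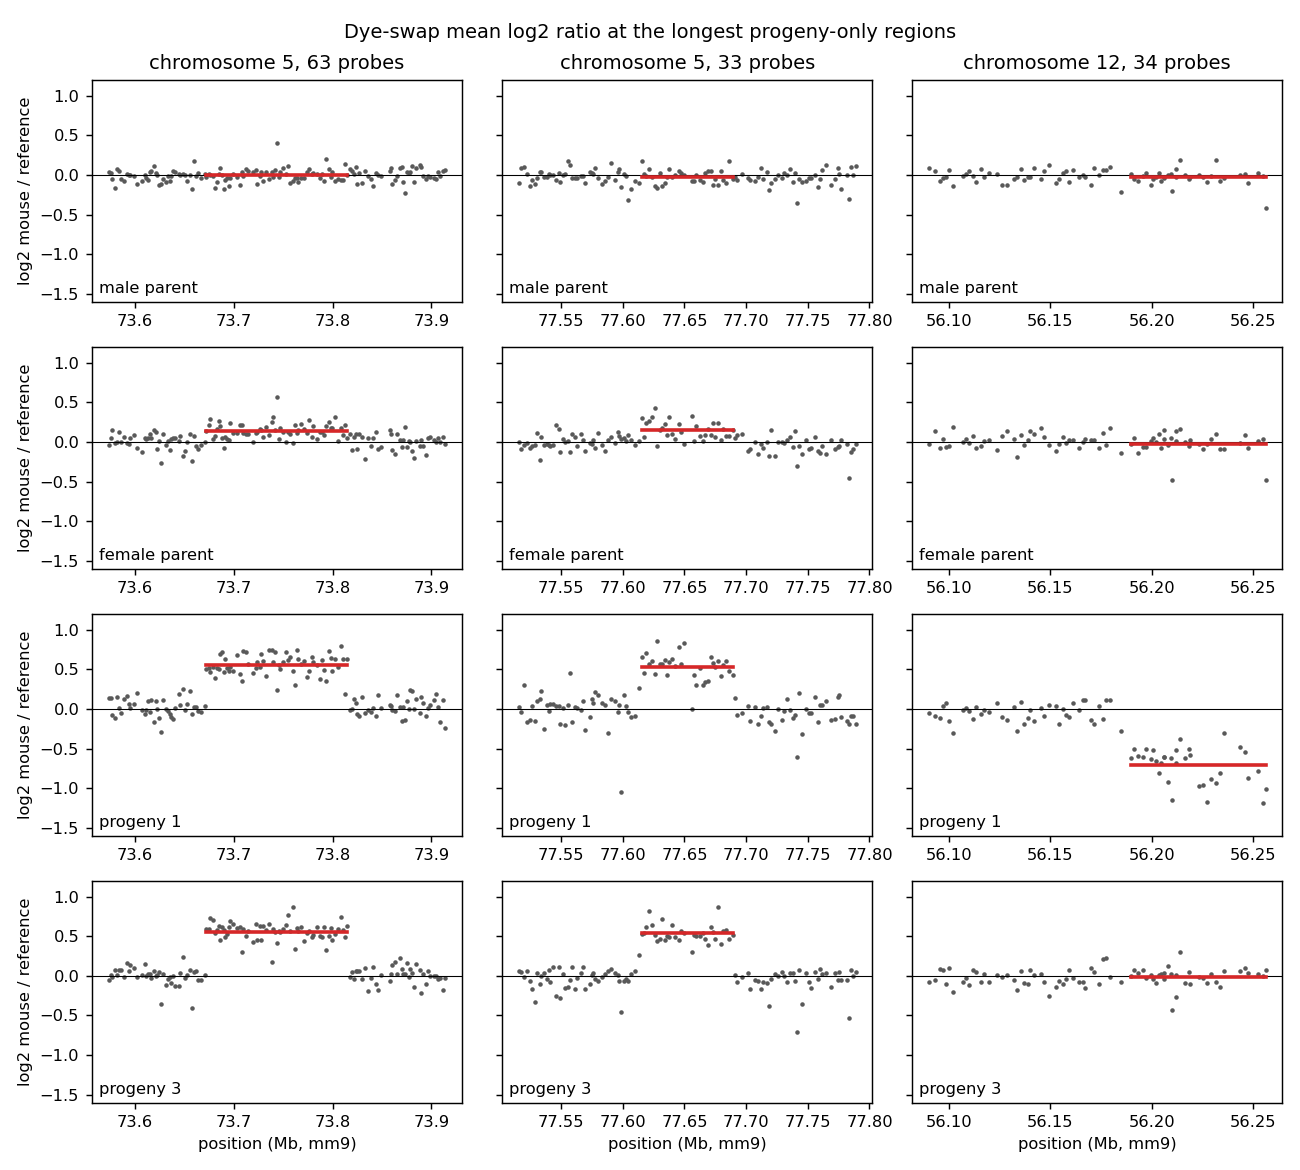
Each point is a probe's log2 ratio of mouse over reference (vertical axis, mean of both dye orientations) against its mm9 position in Mb, in 4 mice (rows) at the 2 chromosome 5 gains and the chromosome 12 loss (columns). Red lines are the region means, which in progeny 1 were 0.56, 0.53 and -0.71, and in the female parent 0.14, 0.15 and -0.02.

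Shorter progeny-only regions with high scores rested on few probes that differed widely, with standard errors close to the means. On chromosome 9, 3 probes from 30748944 to 30753657 had a mean of -0.89 ± 0.74 in progeny 4, from -1.48 with the mouse in Cy5 and -0.30 with the mouse in Cy3. On chromosome 14, 3 probes from 77792512 to 77795479 had a mean of -1.05 ± 0.89 in progeny 5. On chromosome 2, 4 probes from 70082725 to 70090254 had a mean of 0.69 ± 0.50 in progeny 4 and 0.35 ± 0.25 in progeny 8, which was also called, and the lowest progeny was at -0.52. On chromosome 8, 5 probes from 37016811 to 37023927 ranged over the progeny from -0.63 ± 0.48 in progeny 1 to -0.01. On chromosome 10, 5 probes from 22550543 to 22560331 ranged from -0.43 ± 0.47 in progeny 4 to 0.07, with the female parent at -0.24 ± 0.22, and an interval inside this region was also called in the female parent. The calls on chromosomes 9, 14, 2 and 8 were lost after normexp background correction.

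In total 3006 calls were made, of which 2746 were losses, and 2521 (83.9%) spanned 3 probes. They merged into 1736 regions, of which 1544 were progeny only, 59 were carried by a parent and progeny, 45 were classed as parents only and 88 were unresolved. The male parent had 37 calls and the female parent 122, against 154 to 581 per progeny. These counts did not measure copy number change. With probes in random order, which removes any real segment, 2724 calls were still made. Calls of 10 or more probes numbered 43 in real order and 1 in random order. The dye-difference track gave 729 calls, against 3981 on the mean of both orientations without the orientation rule.

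**Figure D2:**
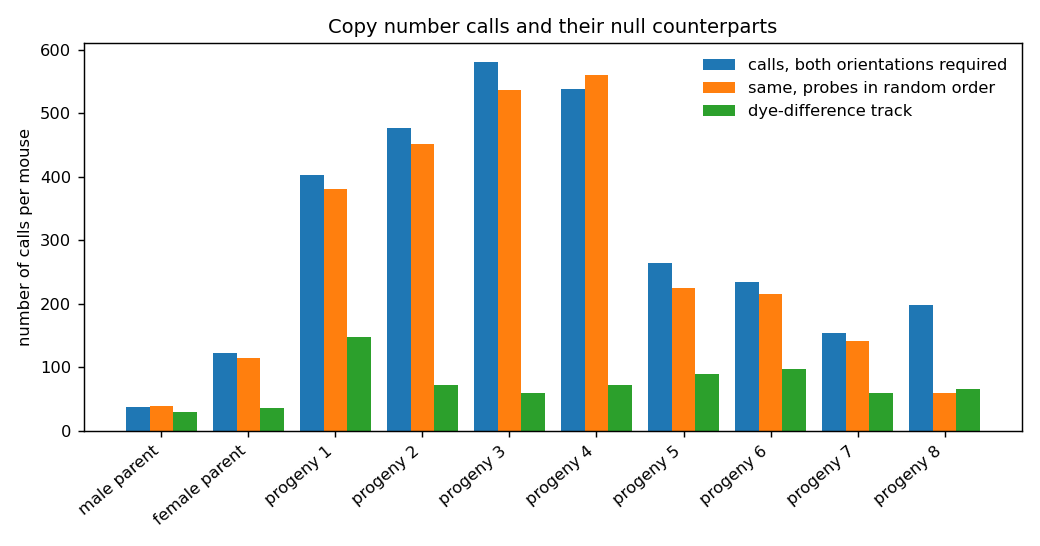
Bars give the number of calls per mouse (vertical axis, from 0) for the real values, for the same values with probes in random order and for the dye-difference track. In progeny 3 these were 581, 537 and 60, and in progeny 8 they were 198, 60 and 66.

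Regions that met the limit in a parent and in progeny were examined as candidates for inherited variants. On chromosome 13, a segment from 100997510 to 101077537 (22 probes, 80028 bp) was at -0.88 ± 0.15 in the female parent and between -0.43 and -0.31 in all 8 progeny, while the male parent was at -0.01. The female parent was not even over the segment: her call, placed where the score was highest, covered 7 probes from 101053361 at -1.65. That is larger in size than her X ratio of 0.93, a contrast of 2 copies to 1. The segment was the only 1 of 56 regions with a single carrying parent that met the limit in 8 of 8 progeny (raw exact binomial p = 0.0078, adjusted p = 0.15), and no region passed the adjusted threshold. This test does not bear on transmission, because its expectation of 1 in 2 assumes a parent with the variant on 1 copy. The number of copies lost in the female parent, whose ratio was larger in size than that of every progeny, was not known, and a parent with a loss on both copies passes it to all progeny. Carriers were also counted by the limit of 0.25, which can part progeny with similar ratios. On chromosome 13, 6 probes from 95701735 to 95712034 were at 0.43 ± 0.38 in the male parent and between 0.18 and 0.38 in the progeny, with the female parent at -0.02.

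On chromosome 8, a segment from 102132083 to 102257578 (45 probes, 125 kb) was at 0.26 ± 0.023 in the female parent and at 0.21, 0.22, 0.22 and 0.29 in progeny 5 to 8. Progeny 1 to 4 lay between -0.02 and -0.01. On chromosome 3, 3 probes from 25417435 to 25432738 were at -1.66 ± 0.33 in the female parent and between -1.65 and -1.53 in progeny 5 to 8. Progeny 1 to 4 lay between -0.01 and 0.04, and the male parent was at 0.05. The ratios of progeny 5 to 8 were larger in size than the female parent's X ratio of 0.93, a contrast of 2 copies to 1. A loss passed on by the female parent alone would leave the male parent's copy, so it would not by itself account for them. Their errors over the 3 probes were 0.27 to 0.37. By the limit of 0.25 in both orientations, only 1 progeny counted as a carrier of the chromosome 8 gain. Both regions thus parted the mice as the X ratio did, and among the progeny this was also a parting by scan day, while the parents shared a day and differed in both regions. Short losses in the female parent and some progeny were also called, with errors close to her means in size or larger. They covered 4 probes of chromosome 6 from 104236953 to 104242812 (female parent -0.63 ± 0.57) and 4 probes of chromosome 11 from 112957750 to 112965298 (-0.52 ± 0.53). A further 5 probes of chromosome 9 from 35853071 to 35865189 were at -0.39 ± 0.44 in the female parent. The chromosome 6 and chromosome 9 regions also parted the mice as the X ratio did. In the chromosome 11 region, the female parent and progeny 5 to 8 were the mice that met the limit in each orientation. Progeny 5 was at -0.31 and -0.34 in the 2 orientations, but at -0.11 over the 3 probes measured in both.

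Regions classed as parents only, in which no progeny met the limit in both orientations over the whole region, were short. The highest score was that of 4 probes of chromosome 11 from 76357341 to 76371516, at 0.61 ± 0.36 in the male parent. On chromosome 16, 4 probes from 40847733 to 40854519 were at -0.37 ± 0.35 in the female parent, and part of them was also called in progeny 8, which was at -0.33 ± 0.36. The other named regions of this class, on chromosomes 4, 8, 11, 15, 16 and 17, had female parent means between -0.40 and 0.37 over 3 to 5 probes, and each was lost in at least 6 of the 13 alternative settings that changed any call. Of these, the chromosome 11 region from 9139583 had its highest-scoring call in the male parent. Over that whole region the male parent was at 0.19 and the female parent at 0.20, so neither met the limit.

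Differences shared by all mice were examined because a variant of the single reference would shift every ratio. No region had a mean past the limit in both orientations in all 10 mice, although a region on chromosome 14 held a call in each of them. On chromosome 10, a segment from 33897213 to 33933441 (19 probes, 36.2 kb) was at -0.60 ± 0.015 in the male parent, -0.56 ± 0.018 in the female parent and between -0.60 and -0.56 in progeny 1 to 7. In progeny 8 its mean was -0.38, from -0.68 with the mouse in Cy5 and -0.08 with the mouse in Cy3. On chromosome 14, a segment from 53387255 to 54386805 (110 probes, 1000 kb), named after its values were seen, was that region, and its mean over all probes lay between -0.27 and -0.20. By limma, the mean over the 10 mice was shifted at 7768 of 949439 autosomal probes, 1046 higher and 6722 lower. A shifted mean does not require that every mouse shares the shift. At probes shifted the same way in all other mice, progeny 8 had slopes on their mean of -0.17 in Cy5 and -0.059 in Cy3. The other mice had slopes from 0.50 to 1.28. These probes were chosen anew for each mouse, 8565 for progeny 8 and 2198 to 3053 for the others. The probes of the other mice also had to agree in sign with progeny 8, so the slopes are not over the same probes. Without progeny 8, 9946 probes passed. Of the shifted probes, 97.0% had no shifted neighbour. The chromosome 10 segment held shifted probes at 18 of its 19 positions and the chromosome 14 segment at 58 of 110. The 10 mice belong to 1 family and share 1 reference, so these p-values do not describe independent animals.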

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

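The tests of a shift shared between mice, of other DNA in the female parent's sample, of equal shares, of a wave slower than the running median, of pairings without the last scan day, and of progeny 8's DNA and ratio compression were chosen after the result was seen. Among 32 sets of 8 progeny values, 8 had a mouse far from the others. In 3 of these the mouse standing apart was the 1 whose high score had named the region, which favours such a gap, so the chance rate of about 1 in 20 does not apply to them: progeny 1 at the chromosome 12 loss (-0.71), progeny 4 at the chromosome 9 region from 30748944 (-0.89) and progeny 5 at the chromosome 14 region from 77792512 (-1.05). Progeny 8, without a call there, stood apart at the chromosome 10 region from 22550543 (0.068, against -0.43 to -0.21). Progeny 8 also had 89 gains against 6 to 30, a correlation of neighbouring probes of 0.095 against 0.002 to 0.010, and 75 long low intervals against 4 to 7.

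The last value standing apart was that of progeny 8 at the chromosome 10 loss, -0.38, which came from its array with the mouse in Cy3 (-0.08, against -0.68 to -0.55 on the other 19 arrays). Compressed ratios on that array were argued against by X, whose ratio there was 1.05 times that on the other array, and DNA from outside the family by the chromosome 13 loss, at -0.32 there. The argument from chromosome 13 holds only if mice outside the family lack this loss, and the reference was the only such mouse measured. Another DNA in the reference channel failed the test set beforehand, which asked for a low slope on the other mice at shared probes on that array alone: it was -0.059 there, but also -0.17 on the other array of progeny 8 and just under 0.5 on an array of the female parent. The bound on other arrays was badly chosen, because the other array of progeny 8 kept the chromosome 10 loss (-0.68) while lacking the shared single-probe shifts, so the slope does not measure the reference channel and the explanation is neither supported nor excluded by it. Of the shared differences looked at afterwards, a chromosome 14 gain from 26694134 to 26953407 was missing on that array (-0.10, against 0.10 to 0.23 on the other 19), but the chromosome 14 loss from 53387255 was kept (-0.24, against -0.30 to -0.19).

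The many short losses in the progeny were largely not segments, since calls with probes in random order reached 90.6% of the real number over all mice, with the exception of progeny 8 (60 against 198). Shifts of the same probes shared between mice may account for part of them: in progeny without a call, the median ratio at other progeny's short losses was -0.20, against 0.00 at random runs, but progeny 8 did not share the shift (0.05, against -0.26 to -0.20 in progeny 1 to 7), while the parents without a call shared part of it (-0.12 and -0.16), so many losses low in the parents too kept the progeny-only class through the limit of 0.25. Scan day may contribute, as 1 of 105 pairings of the progeny, the same-day pairing itself, was as similar as same-day pairs, although the progeny of each day also had the same X dose, the lead was small (mean correlation 0.228, against 0.226 for the next pairing), 5 of 8 progeny correlated best with a progeny of another day, and without the last day, which held progeny 8, the same-day pairing was the most similar of 15 (exact permutation p = 0.067, the smallest possible). Low signal over noise was left undecided, with a Spearman rho of -0.45 over 10 mice (permutation p = 0.19; Pearson r = -0.32, permutation p = 0.36, and -0.37 without the 2 farthest mice), and within the 8 progeny the sign was opposite (rho = 0.07, exact permutation p = 0.88; r = 0.18, exact permutation p = 0.66). Days of 2 mice were too small for values within days, and a biological difference between generations is confounded with scan day and was not tested.

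The partial gain of both chromosome 5 segments in the female parent could reflect mosaicism, with the gain in part of her cells. Relative to progeny 1 and 3 her gain was 22.1% and 24.7%, a difference of -2.51 percentage points (SE 4.35), as a single share of cells would give. DNA of another mouse with both gains in her sample would give equal shares too, so this difference does not tell mosaicism from such DNA. DNA of progeny 1 in her sample was argued against by the chromosome 12 segment, at -0.023 (SE 0.024) where a mixture predicts -0.14. DNA of any mouse with the reference's X dose, progeny 3 among them, was argued against by her mean X ratio of 0.94, where a mixture predicts 0.82. By its SE of 0.33 over probes, the chromosome 3 region, at -1.66, could not decide on progeny 3, where a mixture predicts -1.06. That SE includes differences between probes that the mice share. Over the same 3 probes, progeny 5 to 8 lay between -1.65 and -1.53, so her value there argues against DNA of progeny 3. A wave slower than the running median window was argued against as the whole cause, since subtracting the running median left 0.13 (SE 0.013) and 0.15 (SE 0.020), and her intervals in the long low scan began at the same probes as the progeny gains (73672030 and 77615259), but a wave as short as the segments would not be removed. The test set beforehand for a slow wave asked whether other 63-probe windows reached her value, and 52 did (up to 0.20, on chromosomes 8 and 14), but its verdict was changed to undecided after the result was seen, because all 52 overlapped intervals found in other mice, so a wave is not excluded and mosaicism remains a hypothesis found and tested on the same data.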

How the results depend on the processing

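No paired analysis was possible because each parent group holds 1 mouse and no test compared groups. A minimum of 10 probes and leaving out progeny 8 were added after the data were examined. The counts of calls depended strongly on settings, and the cause was not tested. Calls (3006) numbered 1361 with normexp, 6106 at a score of 5, 587 at 8, 888 with 5 probes, 75 with 10 probes, 910 at a mean of 0.4, and 699 and 875 with the mouse in Cy5 or Cy3 only. Progeny-only regions (1544) numbered 510, 3262, 266, 554, 28, 546, 421 and 522 in the same order, and 1002 with a parent limit of 0.15. Regions in a parent and progeny (59) numbered 37 at a score of 8, 7 with 5 probes, 4 with 10 probes, 380 at a mean of 0.15, 5 at 0.4, and 123 and 182 with the mouse in Cy5 or Cy3 only. Regions with carrier counts away from 1 in 2 numbered 1 with 5 probes and 1 with 10 probes, where fewer regions were tested, against 0, and these counts do not test transmission, because the copies in the parent were not known. Dye-difference calls (729) numbered 2168 at a score of 5, 129 at 8 and 243 with probe dye means kept. Probes with a shifted mean over the mice (7768) numbered 38505 and 50174 with the mouse in Cy5 or Cy3 only and 31718 by adjusted p alone. The female parent's Y ratio (-2.25) was -0.59 with normexp and -1.27 without dim probes, which left 7 of 23 Y probes. Without progeny 8, calls numbered 2808, progeny-only regions 1393 and shifted probes 9946.

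The long regions kept their direction in every signal setting: the chromosome 5 gains of progeny 3 ranged from 0.52 to 0.59 and from 0.51 to 0.55, and the chromosome 12 loss of progeny 1 from -0.72 to -0.65. The correction for GC content and the gene list alternatives were not run. No saturated probes existed, so leaving them out changed nothing.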

Other observations

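The long low scan, added after the data were examined, also found an interval of chromosome 14 from 26694134 to 26953407 (66 probes) at 0.18 in the male parent, 0.16 in the female parent and 0.15 to 0.17 in progeny 1 to 7, with progeny 8 at 0.05.

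Because the chromosome 3 and chromosome 8 regions parted the mice as X did, hybridisation of X or Y sequence to autosomal probes was considered as a hypothesis. The test set beforehand required more called regions to part the mice this way, by a gap of at least 0.1, than in any of the other splits into 5 and 5. It was not met: 10 regions followed X, and 12 followed the split of both parents and progeny 6 to 8 from the rest. The median count over the other splits was 0. Of the 10 regions, 9 were lower in the mice with 2 X and 1, on chromosome 8, was higher, whereas X sequence would raise the ratio in these mice and Y sequence would lower it. The gap was varied afterwards, and X led at 3 of 5 gaps, with 8 regions against 5 at 0.15, 3 against 1 at 0.2 and 2 against 1 at 0.25, but 13 against 50 at 0.05. The count of regions therefore gives no support for the hypothesis at the gap chosen in advance, and its outcome depends on the gap. A count over all called regions also cannot decide on a single region. On chromosome 3 the mice with 2 X lay between -1.66 and -1.53, and the others between -0.01 and 0.05. For that region the hypothesis was left open. Among the progeny the split by X was also a split by scan day, with progeny 1 to 4 on days 2 and 3 and progeny 5 to 8 on days 4 and 5, while the parents, who differ in X, shared a day.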
